A study of Mus musculus with 16 samples.

How the data were processed

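RNA was measured on 16 Illumina bead arrays, 1 per sorted fraction of duodenal crypt cells from transgenic mice of a mixed B6/129S6 background. Per the labels, the mice were 8 to 12 weeks old and received doxycycline at 4 mg/ml in 1% sucrose drinking water for 24 h, which switched on a red fluorescent TdTomato fusion with either oncogenic BRAF(V600K) or luciferase as a control. Crypts were released with EDTA, digested to single cells with trypsin and DNase, and sorted by green fluorescence (an EGFP reporter of the stem cell gene Lgr5) and red fluorescence (the transgene). The 4 gates were G (green high, red low), RG (both high), R (red high, green low) and NEG (both low). RNA was extracted on RNeasy Micro columns and labelled by the NuGen procedure, per the labels' protocols.

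The deposited intensity values were used as they stand. The submitters' processing notes name GenomeStudio, with its version not given in the sources used here, and nothing used here states the normalization. From the values, the deposited table holds linear intensities from 55.7 to 40121.2 for 25697 probes. The sorted values of the 16 arrays agree to within 1.2, so they were quantile-normalized together and all arrays have the same distribution (array medians 118.9 to 119.9). As the lowest value is 55.7, background appears not to have been subtracted, though no source used here states this. Fold changes are then on the scale of log2(intensity) with background included and would understate the true change, most for dim genes. A table of non-normalized signals was not used here, because its 32 columns (16 of signals and 16 of detection p-values) carry running numbers that match no array's labels. The background correction from detection p-values and the detection filter that had been chosen before the data were examined were therefore not applied. The columns were not matched to arrays by their values. In their place, log2 of the deposited intensities was tested, and a probe was kept if it lay above the array median on at least 2 arrays. The tests, groups, comparisons, gene lists and the rule for the genes named in the text were otherwise kept as chosen before the data were examined.

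Probes were named through the platform annotation, with symbols checked by Entrez identifier against a RefSeq gene table of assembly GRCm38.p6. Of the probes, 23978 had 1 gene symbol, 0 had several and 1719 were unnamed; 23962 matched by identifier and 0 symbols changed. The filter kept 16005 probes, 15000 of them named. Each gene was represented by its kept probe of highest mean log2 intensity over all 16 arrays, which gave 10607 genes tested, 2905 of them with more than 1 kept probe. A gene whose tested probe lay at or below the array median on every array of a group is called dim there and has only a bound. Its change is given as "at least N-fold", the mean of the brighter group over the mean of, per array, the higher of the array median and the gene's own signal. The bound is also given for a gene above the median on some arrays of a group only, if its mean there lies under the median; for others of this kind the number of such arrays is given. In the comparisons of 2 groups, a list's median was also taken with dim genes at their bound and genes dim in both groups left out, and it is printed beside the median where they differ by 0.05 or more. Braf and Mki67 had 0 probes in the table and are not analysed here.

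Per the labels, arrays with the same number within a line came from the same mouse, and the numbers are separate mice: 3 for the BRAF line, with 4 gates each, and 2 for the luciferase line, with gates G and RG. The pairing was also visible in the values. Deviations from the group means correlated above 0.1 in 18 of 18 pairs of arrays from the same BRAF mouse (median r 0.319, across genes, which are not independent replicates). The median was -0.160 for arrays from different BRAF mice. Deviations within a group cancel out, so this negative value follows from the positive one and adds no support of its own. For the 2 luciferase mice, same-mouse pairs had r 0.0457. No chip, slide or processing day is named in the sources used here, so no technical batch could be tested. The BRAF and luciferase transgenes were carried by different lines of mice, and line and transgene cannot be separated.

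The 6 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 10 residual degrees of freedom and 5.26 prior ones), so that the small groups share 1 estimate of the spread. This takes the spread to be equal in all groups. Estimated array weights, low for noisy arrays, were 2.81 in luciferase G and 0.410 in luciferase RG. They ran from 1.06 to 2.32 in BRAF G, from 0.729 to 1.03 in BRAF RG and from 0.276 to 1.48 in BRAF R. The p-values may thus be too small for luciferase RG and BRAF R and too large for G against G. With these weights fewer genes were called for luciferase RG against G (1003, against 1261) and BRAF RG against luciferase RG (625, against 1761). More were called for BRAF RG against G (292, against 85) and R against NEG (1464, against 1332). There were 8 comparisons, each two-sided, with Benjamini-Hochberg adjustment over the 10607 genes and a threshold of 0.05. Errors of log2 changes are the fit's standard errors (SE), and means of groups carry standard deviations (SD). Mouse was not a term of this fit; fits with mouse as a fixed and as a random block were among the alternatives. The value with mouse as a block is that of the fixed block unless a random one is named, and it is given beside each result whose call it changes. For lists under the random block, camera was run on values and design whitened by the correlation within a mouse. An exact permutation test of 3 arrays against 3, without the pairing, cannot give a p below 0.1. With the arrays paired by mouse the floor is higher still, so no exact test was run on single genes. The number of arrays limits the precision of every value.

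A set of 15 gene lists was fixed before the data were examined: ERK pathway output, immediate-early genes and EGF-family ligands, intestinal stem cell, Wnt target, Paneth cell, goblet cell, enteroendocrine cell, tuft cell, absorptive enterocyte, cell cycle, p53 targets and CDK inhibitors, regeneration and YAP response, heat shock and dissociation stress, leukocyte, and stroma, muscle and endothelium. Each was tested in each comparison with camera (preset correlation 0.01), adjusted over the 15 lists, and again with the correlation estimated from the data. Camera compares a list with all other genes. A member counts as risen or fallen if it passed the threshold over all genes; the count adjusted over the list alone is given beside it. The stem cell and Wnt lists share 7 tested members.

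The genes named were fixed by rule: the 10 largest rises and 10 largest falls (5 and 5 outside the first 2 comparisons) among genes past the threshold with the same direction in every mouse, up to 4 members of each list with the smallest p, and Lgr5, Dusp6, Spry4, Ascl2 and Olfm4 throughout. Where no within-mouse pair existed, the groups had not to overlap. Not every gene so picked is printed in every comparison. Genes named outside this rule are marked as such.

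The steps were tested on simulated data over the 10607 genes, with 200 genes changed in 5 runs per comparison. For BRAF RG against BRAF G, 70% of the genes changed by a log2 of 1 and 97.8% of those changed by 2 were recovered, with 9 false calls per run; for BRAF R against BRAF NEG the shares were 70.6% and 96.4%. With the 2 luciferase mice they were 44% and 93% for luciferase RG against G, and 22.2% and 80.4% for the difference between the lines. A list shifted by a log2 of 0.5 was called in 20 of 20 runs, and 2 of 272 lists left unshifted were called. The simulated genes varied independently of each other, each with the same spread in all groups. These shares therefore do not cover lists whose members vary together. In the data the estimated correlation within a list reached 0.696 (Paneth list).

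The alternatives were a constant of 16 added before the log, normexp background correction of the deposited intensities with offsets of 16 and 50, cyclic loess on top of the deposited normalization, no filter and a stricter filter on dim probes, the mean of a gene's probes, mouse as a fixed or a random block, array weights, a trended and robust variance prior, only the compared groups in the fit, a fold threshold, and each mouse or doubtful array left out. Figures were drawn with matplotlib 3.10.9.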

Results

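Expression was measured in sorted crypt cells of the mouse duodenum 24 h after induction of a TdTomato-tagged BRAF(V600K) transgene, an oncogenic form of the BRAF kinase that activates the MEK and ERK kinases, or of a TdTomato-luciferase control. The 16 arrays fall into 6 groups. In the BRAF line, the gates G, RG, NEG and R were each measured in 3 mice, and in the luciferase line the gates G and RG were each measured in 2 mice. G cells were high for the Lgr5-EGFP stem cell reporter and low for the red transgene, RG cells were high for both, R cells were high for red only, and NEG cells were low for both. Within a line, the gates came from the same animals. All arrays have the same intensity distribution, with medians from 118.9 to 119.9. Log2 changes below are differences of log2 intensity.

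Arrays of a group resembled each other least in the red gates. Pearson's r across probes, which are not independent replicates, was 0.990 between the 2 luciferase G arrays and 0.924 between the 2 luciferase RG arrays. In the BRAF line the mean r of an array with its group was 0.977 to 0.980 in G, 0.956 to 0.959 in RG, 0.968 to 0.974 in NEG and 0.918 to 0.939 in R. The lowest value, 0.918, belonged to R of mouse 1. In a principal component analysis, the first 3 components held 30.2%, 20.3% and 10.1% of the variance. BRAF R and luciferase RG lay at the high end of the first component, and the 3 NEG arrays lay apart on the third.

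**Figure D1:**
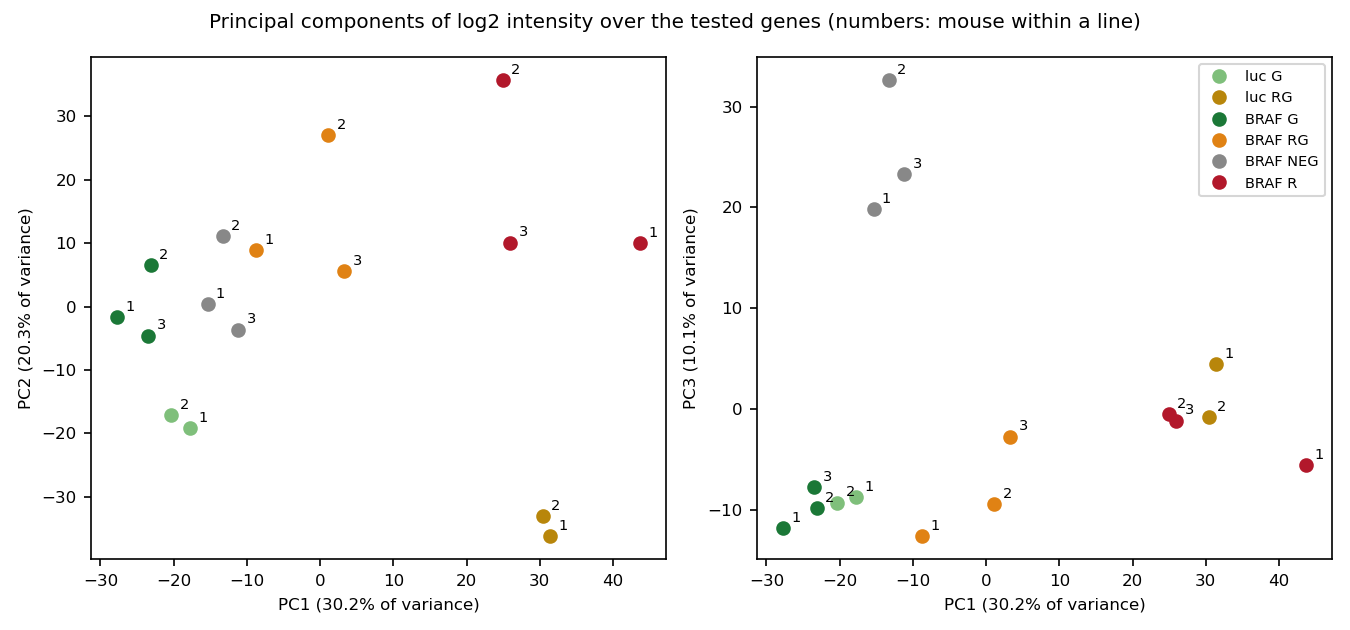
Principal components of log2 intensity over the 10607 tested genes, with the first component (30.2% of the variance) on the x axis of both panels and the second (20.3%) and the third (10.1%) on the y axes. Each point is 1 of 16 arrays, coloured by group and numbered by mouse within its line. The 3 BRAF NEG arrays lie between 19.8 and 32.7 on the third component, above all other arrays, and the 2 luciferase RG arrays are lowest on the second.

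The comparison of RG with G in the BRAF line sets Lgr5-EGFP-high cells that were high for the BRAF transgene beside such cells that were low for it. It holds whatever else differs between the red gates as well as the transgene's effect. Of the 60 genes higher in RG here, 31 were also higher in luciferase RG than in luciferase G, S100a6 (2.00), Cdkn1a (2.09) and Tph1 (3.09) among them. Genes of the regeneration and YAP response list, which marks crypts under repair, were higher in RG: S100a6, a calcium-binding protein, by a log2 of 1.85 ± 0.21 (SE; adjusted p 0.00177, limma), from 10.74 ± 0.16 to 12.59 ± 0.29 (mean log2 intensity ± SD, 3 mice each), and the annexins Anxa10 by 2.30 ± 0.45 (adjusted p 0.0229) and Anxa2 by 1.42 ± 0.21 (adjusted p 0.00502). Dusp6, a phosphatase that acts on ERK and is transcribed downstream of it, rose by 1.58 ± 0.31 (adjusted p 0.0229). The cell cycle inhibitor genes Cdkn2b (2.01 ± 0.30, adjusted p 0.00502; above the array median on 1 of 3 G arrays) and Cdkn1a (1.54 ± 0.21, adjusted p 0.00392) rose. Olfm4, a stem cell marker, fell by 0.84 ± 0.19 (adjusted p 0.0469). Tuft cell genes fell, among them Dclk1, which was at least 2.36-fold lower (adjusted p 0.00515), and Trpm5, a cation channel of tuft cells, which was at least 2.16-fold lower (adjusted p 0.0155). Each of these genes moved in the same direction in 3 of 3 mice.

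In all, 85 genes passed the threshold, 60 higher and 25 lower in RG. The 10 largest rises were Emp1 (2.53), Anxa10, Tph1 (2.24), Lgals3 (2.23), Bex2 (2.20), Anxa3 (2.09), Cd177 (2.07), Tac1 (2.06), S100a14 (2.06) and Cdkn2b, with adjusted p from 0.00502 to 0.0426. Anxa10, Tph1 and Anxa3 lay above the array median on 2 of 3 G arrays. Tph1 is the rate-limiting enzyme of serotonin synthesis in the gut and Tac1 encodes the precursor of substance P, both products of enteroendocrine cells. Among the 10 genes picked for the lowest log2 differences, Vav1 (-2.02), Fyb (-1.85), Tspan6 (-1.74), Alox5ap (-1.45) and Kctd12 (-1.41) were measured in both gates, Vav1, Fyb and Alox5ap on 2 of 3 RG arrays. Siglecf (at least 2.92-fold), Pygl (at least 3.25-fold), Lrmp (at least 2.38-fold), Dclk1 and Trpm5 were dim in RG and have no rank. Adjusted p ran from 0.00177 to 0.0277. Vav1, Siglecf and Fyb are also known from blood cells, whose list did not shift here (median 0.07, or 0.00 without the 10 members dim in both gates and with 4 others at their bound; camera adjusted p 0.33). Lgr5 itself had a log2 difference of -1.06 ± 0.32, lower in 3 of 3 mice, which did not pass (adjusted p 0.198). Spry4, at least 1.62-fold higher in RG, did not pass either.

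By list, 6 of the 15 tested members of the regeneration and YAP response list rose and 0 fell (9 rose when adjusted over the list alone), with a median of 1.24 (1.10 with 3 dim genes at their bound; camera adjusted p 8.21e-15). Of 19 ERK pathway output genes, 2 rose, Dusp6 and Dusp4 (1.16 ± 0.25), and 5 rose when adjusted over the list alone. The median was 0.41 (camera adjusted p 1.24e-08). Plaur (2.09) and Fosl1 (at least 2.35-fold) had adjusted p of 0.0649 and 0.0753, which became 0.00139 and 0.0129 with mouse as a block. Immediate-early genes and EGF-family ligands rose as a list (median 0.76, or 0.49 with 5 dim genes at their bound; camera adjusted p 1.03e-07), with 0 of 16 members past the threshold over all genes and 8 adjusted over the list alone. Klf6 (1.03) and Hbegf (1.51) had adjusted p of 0.0807 and 0.273, and 0.00819 and 0.0121 with mouse as a block, with which Dusp1 (1.41) passed too (0.0204, against 0.146 without it). The intestinal stem cell list fell (median -0.57, camera adjusted p 1.27e-11), with 1 of 25 members past the threshold and 10 adjusted over the list alone. Aqp4 (-1.01) had adjusted p of 0.119, and 0.00948 with mouse as a block. The Wnt target list, which shares 7 members with it, fell as well (median -0.31, camera adjusted p 5.45e-05), with 0 of 15 past the threshold and 3 adjusted over the list alone. With an estimated correlation these 5 lists kept their calls at larger values. The camera adjusted p was then 0.00893 for regeneration, 0.0278 for ERK, 0.0438 for immediate-early, 0.0102 for stem cell and 0.0278 for Wnt.

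Of 11 tuft cell genes, 4 fell and 0 rose (8 fell when adjusted over the list alone), with a median of -0.72 (-0.55 with 6 dim genes at their bound; camera adjusted p 1.32e-14, and 0.0104 with an estimated correlation). Of 19 enteroendocrine genes, 4 rose, Sct (1.31), Neurod1 (1.38), Tac1 and Tph1, and 13 rose and 1 fell when adjusted over the list alone. Their median was 0.99 (camera adjusted p 3.92e-15; adjusted p = 0.0503 with an estimated correlation). The goblet list (median 0.57, camera adjusted p 2.81e-09) lost its call with an estimated correlation (adjusted p = 0.0677), as did the Paneth list (median 0.63, camera adjusted p 3.18e-05; adjusted p = 0.196 with an estimated correlation) and the absorptive enterocyte list (median 0.55, camera adjusted p 1.24e-08; adjusted p = 0.161 with an estimated correlation). In each of these 3 lists 0 members passed the threshold over all genes; 8, 2 and 1 rose when adjusted over the list alone. Bcas1, Tff3, Zg16, Ang4, Nupr1 and Krt20 had adjusted p of 0.106, 0.0649, 0.139, 0.0671, 0.255 and 0.0596, and of 0.00208, 0.0121, 0.0131, 0.0316, 0.0148 and 0.0176 with mouse as a block. The list of p53 targets and CDK inhibitors was called (median 0.09, or 0.04 with 2 dim genes at their bound, camera adjusted p 0.00514, and 0.0278 with an estimated correlation) on 2 members of 16, Cdkn1a and Cdkn2b. Both inhibit cyclin-dependent kinases; 3 rose when adjusted over the list alone. Cell cycle genes had a median of -0.18 that did not pass (camera adjusted p 0.0557, 0 of 32 members past the threshold over all genes or over the list alone). The lists for heat shock and dissociation stress (median 0.13, camera adjusted p 0.375) and for stroma, muscle and endothelium (0.10, or 0.17 without 1 member dim in both gates; 0.0925) did not pass either. With mouse as a block, 201 genes passed, 151 higher and 50 lower, and they include all 85. Without mouse 1, 2 or 3, the count was 59, 28 or 17. Of the 30 genes picked by the fixed rule that passed, 3 (S100a6, Fyb and Pygl) passed in each of these fits. The cell cycle list passed without mouse 1 (camera adjusted p 0.0133).

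**Figure D2:**
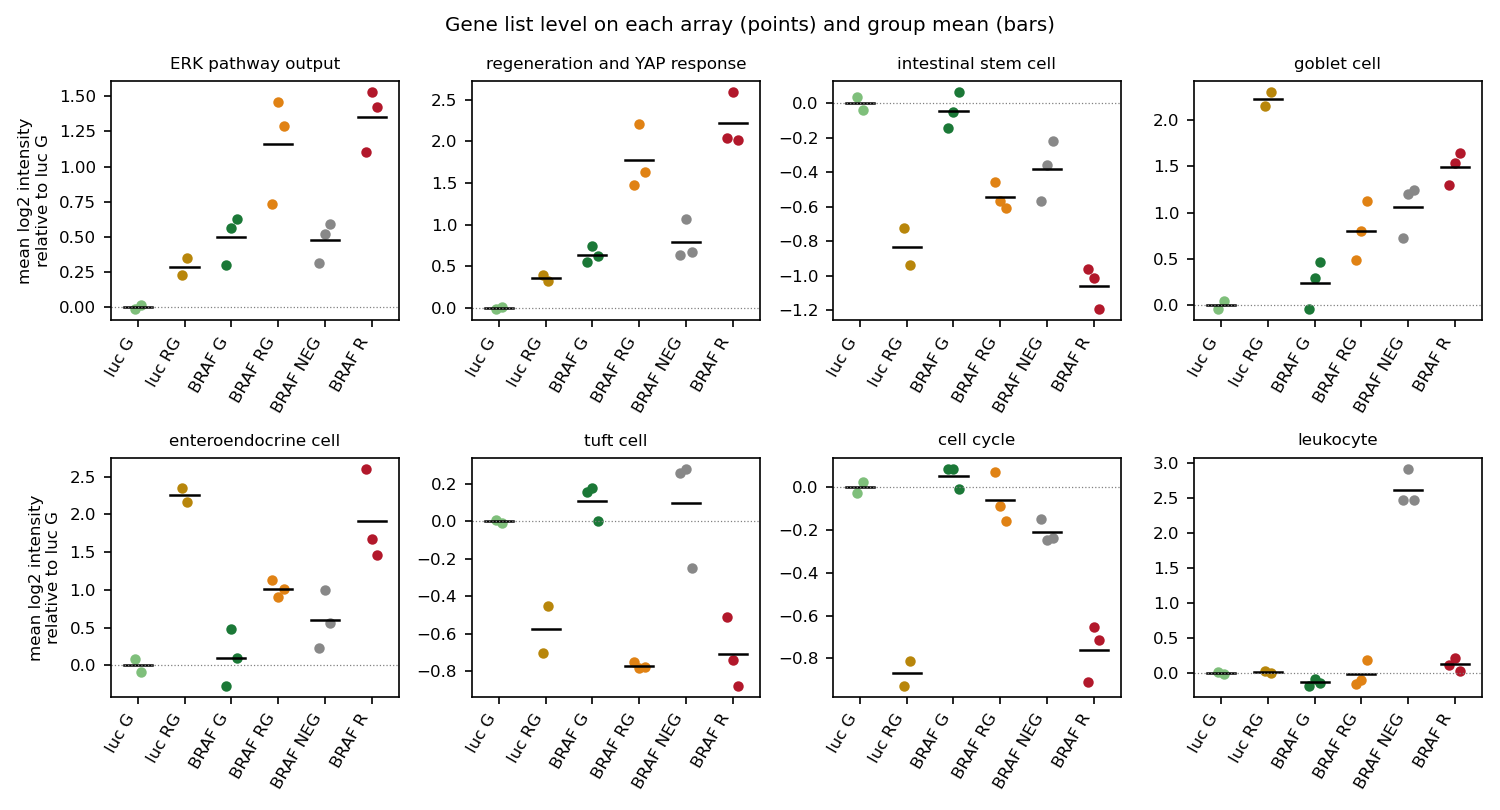
Mean log2 intensity of the tested members of 8 gene lists on each array (points, coloured by group) and the mean of each group (bars), relative to the mean of the luciferase G arrays (dotted line); the x axis gives the group, and the y axis, in log2 units, differs between panels. The regeneration and YAP response list lies at 1.77 ± 0.38 in BRAF RG and 2.22 ± 0.32 in BRAF R (mean ± SD, 3 mice), against 0.36 ± 0.05 in luciferase RG (2 mice), where 6 of its 15 members were dim in both gates, and the leukocyte list is high in BRAF NEG alone (2.62 ± 0.26).

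The comparison of R with NEG does the same for cells low for Lgr5-EGFP, for which there were no luciferase arrays. Leukocyte genes were far lower in R. The chemokine Ccl5 fell from 12.28 ± 0.38 in NEG to 7.71 ± 0.70 in R (mean log2 intensity ± SD, 3 mice each), a change of -4.57 ± 0.42 (SE; adjusted p 3.71e-06, limma), and Gzma, a granule protease of cytotoxic lymphocytes, changed by -4.35 ± 0.30 (adjusted p 1.5e-07). Of 20 leukocyte genes, 18 fell and 0 rose (the same counts when adjusted over the list alone), with a median of -2.72 (camera adjusted p 2.48e-30), or -2.43 with 11 genes that were dim in R at their bound. NEG was the group in which these transcripts were abundant: Ccl5 averaged 5089 intensity units in NEG and 108.2 in G. The counts of genes lower in R than in NEG therefore include the leukocyte genes. Of the 774 genes lower in R, 196 were also lower in G than in NEG, a comparison with the same NEG arrays. Genes and lists higher in R may likewise depend on the makeup of NEG, which was not tested.

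Outside the leukocyte list, the regeneration and ERK lists were called higher in R, the latter not with an estimated correlation (adjusted p = 0.0855 with an estimated correlation). Anxa10 rose by 3.45 ± 0.45 (adjusted p 0.000117), S100a6 by 1.62 ± 0.21 (adjusted p 0.000119) and Krt7, a keratin, by 1.88 ± 0.25 (adjusted p 0.000157). Dusp6 rose by 1.89 ± 0.31 (adjusted p 0.000936), Dusp4 by 1.86 ± 0.25 (adjusted p 0.000199) and Plaur, the urokinase receptor, by 2.71 ± 0.49 (adjusted p 0.002), and Spry4, a feedback inhibitor of the pathway, was at least 2.23-fold higher (adjusted p 0.00985). Ccnd1, the cyclin D1 gene and a member of the ERK list, fell by 1.11 on the log2 scale (SE 0.18, adjusted p 0.00107), while another of its probes had the opposite sign. Cell cycle genes fell, among them the replicative helicase subunits Mcm4 (-1.33 ± 0.18, adjusted p 0.000149) and Mcm7 (-1.55 ± 0.28, adjusted p 0.00216). Stem cell genes fell too, with Cdca7 at -1.61 ± 0.18 (adjusted p 2.68e-05) and Olfm4 at -1.19 ± 0.19 (adjusted p 0.000637). Lgr5 and Ascl2, each above the array median on 2 of 3 R arrays, did not pass. Cdkn1a rose by 1.91 ± 0.21 (adjusted p 2.08e-05).

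Here 1332 genes passed, 558 higher and 774 lower in R. The largest rises were Anxa10, Cd86 (3.37), Sprr1a (3.35), Gprc5a (3.25), Scg2 (3.09), Tac1 (2.95), Tph1 (2.90), Mapk11 (2.78) and Plaur, with adjusted p from 5.26e-05 to 0.00503. Of the genes picked with them, Aldh1a3 was at least 6.31-fold higher, as its mean in NEG lay under the array median. Anxa10 and Cd86 lay above it on 2 of 3 NEG arrays. The 10 genes picked for the lowest log2 differences are known from leukocytes: Ccl5, Gzma and Laptm5 (-4.33) were measured in both gates, Tyrobp (at least 11.9-fold) on 1 of 3 R arrays, and Ccl4 (at least 13.4-fold), Itgae (at least 13.5-fold), Cd200r2, Clec10a (at least 8.04-fold), Xcl1 (at least 8.63-fold) and Cd3d (at least 9.04-fold) were dim in R and have no rank. Of the 60 genes higher in RG than in G, 59 were higher in R than in NEG as well, against 3.16 expected of independent lists, and 19 of the 25 lower genes were lower in both, against 1.82. The comparisons share mice but no arrays. Across all 10607 genes the log2 changes correlated at Pearson's r 0.609 and Spearman's rho 0.573, over genes, which are not independent replicates.

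By list, 10 of 15 regeneration and YAP response genes rose (11 adjusted over the list alone; median 1.31, camera adjusted p 1.93e-09), and 10 of 25 stem cell genes fell (14 adjusted over the list alone; median -0.83, or -0.70 with 2 dim genes at their bound, camera adjusted p 1.82e-07). Of 32 cell cycle genes, 10 fell and 0 rose (12 fell when adjusted over the list alone; median -0.52, camera adjusted p 5.71e-08). Those 3 lists and the leukocyte list held with an estimated correlation, at larger values (camera adjusted p 0.0242, 0.0249, 0.0249 and 0.00395, in this order). Of 19 ERK output genes 9 rose and 1 fell (13 and 1 adjusted over the list alone; median 0.81, or 0.67 with 3 dim genes at their bound, camera adjusted p 4.73e-06; adjusted p = 0.0855 with an estimated correlation). Of 16 immediate-early genes and EGF-family ligands 8 rose (9, and 1 fell, adjusted over the list alone; median 0.85, or 0.60 with 3 dim genes at their bound, camera adjusted p 0.000214; adjusted p = 0.153 with an estimated correlation), among them the ligands Hbegf (2.08) and Btc (1.75, measured on 2 of 3 NEG arrays). Of 19 enteroendocrine genes 15 rose (17, and 1 fell, adjusted over the list alone; median 1.39, camera adjusted p 1.61e-11; adjusted p = 0.108 with an estimated correlation). Of 11 tuft cell genes 7 fell (8 adjusted over the list alone; median -0.63, camera adjusted p 1.3e-05; adjusted p = 0.104 with an estimated correlation), Dclk1 at least 3.01-fold. Goblet genes (2 rose, Klk1 and Tff3, and Atoh1 fell; median 0.52, camera adjusted p 0.00232) and enterocyte genes (2 rose, Krt20 and Prap1; median 0.70, camera adjusted p 1.02e-05) had adjusted p of 0.313 and 0.287 with an estimated correlation; adjusted over the list alone, 6 rose and 1 fell, and 4 rose. With mouse as a block, Spdef (0.67), Fabp1 (1.17), Slc2a5 (1.09) and Myc (-1.01) passed as well, with adjusted p of 0.0178, 0.0183, 0.00475 and 0.0284, against 0.0826, 0.0621, 0.0621 and 0.0593 without it.

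The remaining lists did not pass in R against NEG. The Wnt list had a median of -0.32 (camera adjusted p 0.0541, 0.0489 with mouse as a fixed block and 0.0536 as a random one), with 3 of 15 members lower, among them Axin2 (-1.66 ± 0.28, adjusted p 0.00121), a feedback inhibitor of the Wnt pathway. The Paneth list (median 0.17, camera adjusted p 0.285, with a median of -0.327 without mouse 1 and 0.460 without mouse 2; Nupr1 had adjusted p of 0.107, and 0.00875 with mouse as a block), p53 targets and CDK inhibitors (0.05, 0.298), heat shock and dissociation stress (0.20, 0.511) and stroma, muscle and endothelium (0.27, or 0.20 with 1 dim gene at its bound, 0.182) did not pass. Fitted on these 6 arrays alone, 601 genes passed, and without mouse 1, 2 or 3 the count was 679, 612 or 705. Without the R array of mouse 1, which correlated least with its group, it was 1167. Of the 62 genes picked by the fixed rule that passed, 45 passed in each of these fits. The Wnt list passed without mouse 1 (camera adjusted p 0.00637).

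**Figure D3:**
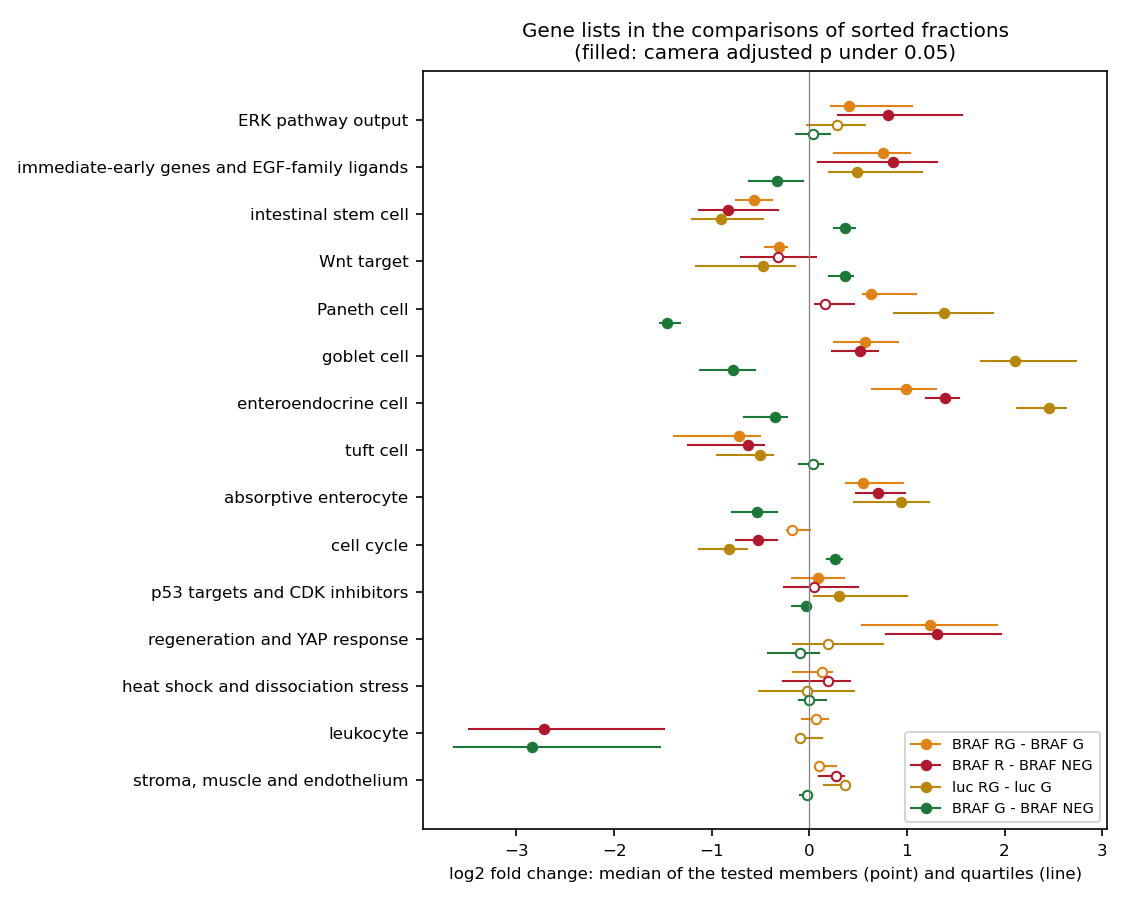
Log2 fold changes (x axis) of the 15 gene lists (y axis) in 4 comparisons, as the median of the tested members (points) with their quartiles (lines); filled points have a camera adjusted p under 0.05 with the preset correlation. The regeneration and YAP response list has medians of 1.24 and 1.31 in the BRAF comparisons of RG with G and of R with NEG and 0.20 in luciferase RG against G, where 6 of its 15 members were dim in both gates. With dim genes at their bound and those 6 left out, the medians are 1.10, 1.31 and 0.67. The leukocyte list lies at -2.72 and -2.84 in the comparisons with NEG (-2.43 and -2.44 with dim genes at their bound).

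The comparison of RG with G in the luciferase line sets the same gates side by side with no BRAF transgene. The goblet and enteroendocrine lists were called higher in RG, the latter not with an estimated correlation (adjusted p = 0.0565 with an estimated correlation). Zg16, a goblet cell granule protein, rose by 3.12 ± 0.33 (SE; adjusted p 0.000122, limma), from 10.49 ± 0.09 to 13.61 ± 0.05 (mean log2 intensity ± SD, 2 mice each). Bcas1 rose by 3.60 ± 0.44 (adjusted p 0.00023), Tac1 by 3.24 ± 0.49 (adjusted p 0.000821) and Atoh1, the transcription factor that sets secretory fate, by 1.86 ± 0.21 (adjusted p 0.000144). Cell cycle genes were lower, with Mcm7 at -2.26 ± 0.35 (adjusted p 0.000977; above the array median on 1 of 2 RG arrays) and Mcm2 at -1.71 ± 0.22 (adjusted p 0.000362). Lgr5 fell by 1.69 on the log2 scale (SE 0.39, adjusted p 0.0118), lower in 2 of 2 mice.

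Of the 1261 genes past the threshold, 542 were higher and 719 lower in RG, and with cyclic loess on top of the deposited normalization the split was 678 of 1196 higher. The largest rises were Bcas1, Tac1, Ccl9 (3.15), Zg16 and Tph1 (3.09), and the largest falls measured in both gates were Phtf2 (-2.40), Mcm7, Tctex1d2 (-2.07) and Tns4 (-2.01), with adjusted p of up to 0.02. Gas7, dim in RG, was at least 4.32-fold lower. All 15 goblet genes rose (median 2.10, camera adjusted p 1.01e-21), also when adjusted over the list alone, and 16 of 19 enteroendocrine genes rose (19 adjusted over the list alone; median 2.45, camera adjusted p 1.73e-19; adjusted p = 0.0565 with an estimated correlation). Of 32 cell cycle genes 16 fell and 0 rose (25 fell when adjusted over the list alone; median -0.82, camera adjusted p 1.5e-12), and of 25 stem cell genes 11 fell and 0 rose (14 fell when adjusted over the list alone; median -0.91, camera adjusted p 4.73e-07). With an estimated correlation the goblet, cell cycle and stem cell lists held at camera adjusted p of 0.0266, 0.0167 and 0.0383. Of 12 Paneth genes 4 rose, Mptx1, Nupr1, Mmp7 and Ang4 (5 adjusted over the list alone; median 1.38, camera adjusted p 0.000333; adjusted p = 0.298 with an estimated correlation). Of 22 enterocyte genes 2 rose, Krt20 and Mttp (10 adjusted over the list alone; median 0.94, camera adjusted p 2.18e-05; adjusted p = 0.298 with an estimated correlation).

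Tuft cell genes moved the other way, as in the BRAF line: 3 of 11 fell, Alox5ap, Rgs13 and Trpm5 (4 adjusted over the list alone; median -0.50, or -0.37 with 6 dim genes at their bound, camera adjusted p 0.00479; adjusted p = 0.275 with an estimated correlation). The Wnt list fell (4 of 15 members, 7 adjusted over the list alone; median -0.47, camera adjusted p 0.00479; adjusted p = 0.111 with an estimated correlation). Among immediate-early genes and EGF-family ligands 3 rose, Klf4 (2.15), Fosb (2.57) and Fos (1.51), and Myc, of which 1 other probe had the opposite sign, fell (4 rose and 1 fell when adjusted over the list alone; median 0.49, or 0.76 with 1 dim gene at its bound and without 4 dim in both gates, camera adjusted p 0.00479; adjusted p = 0.275 with an estimated correlation). Among p53 targets and CDK inhibitors 3 rose, Cdkn1a (2.09), Cdkn1c (1.96) and Tnfrsf10b (4 of its other probes had the opposite sign), and 2 fell (4 and 2 adjusted over the list alone; median 0.31, or 0.38 without 1 member dim in both gates, camera adjusted p 0.0185; adjusted p = 0.0688 with an estimated correlation). Of the ERK list, Dusp4 (1.56, measured on 1 of 2 G arrays) and Etv5 (1.06) rose and Ccnd1 (-0.88) fell. The list did not pass (median 0.29, or 0.13 with 3 dim genes at their bound and without 3 dim in both gates; camera adjusted p 0.0807). Dusp6 had a log2 difference of 0.93 ± 0.38 (adjusted p 0.124, and 0.0325 with mouse as a block). Of the regeneration list, S100a6 (2.00) and Krt7 (1.28) rose. The list's median was 0.20, or 0.67 without the 6 of 15 members dim in both gates and with 1 other at its bound (camera adjusted p 0.0622, 0.0302 with mouse as a fixed block and 0.051 as a random one). With mouse as a block, Anxa2 (0.72), Anxa3 (at least 1.59-fold), Vil1 (0.86), Slc2a5 (1.35), Il17rb (at least 1.27-fold lower) and Ddit3 (0.91) passed as well, with adjusted p of 0.0156, 0.0321, 0.0261, 0.00515, 0.0344 and 0.0365, against 0.0853, 0.253, 0.0525, 0.0616, 0.0748 and 0.0657 without it. Heat shock and dissociation stress (median -0.02, camera adjusted p 0.99), leukocyte (-0.10, 0.99; 11 members were dim in both gates, and the median of the others was 0.00 with 4 at their bound) and stroma, muscle and endothelium (0.36, or 0.14 with 3 dim genes at their bound, 0.164) did not pass. Of the 60 genes higher in BRAF RG than in BRAF G, 31 were higher in luciferase RG than in luciferase G too, against 3.07 expected of independent lists, and 16 of the 25 lower genes were lower in both, against 1.69. These comparisons share no arrays or mice. Fitted on these 4 arrays alone, 455 genes passed, and without mouse 1 or 2 the count was 341 or 498, fits in which the remaining mouse is taken to vary like the other groups. In all, 17 of the 53 genes picked by the fixed rule that passed did so whichever mouse or RG array was left out. The immediate-early, Wnt and tuft lists lost their calls without mouse 1 (camera adjusted p 0.0660, 0.0624 and 0.0730), and p53 targets and CDK inhibitors without mouse 2 (0.110).

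Whether the change from G to RG differed between the lines was tested directly, as the BRAF difference minus the luciferase difference. Cell cycle genes, which were lower in luciferase RG, differed upward: the median of 32 members was 0.80 (camera adjusted p 3.11e-12), with Mcm2 at 1.51 ± 0.29 (SE; adjusted p 0.037, limma) and 17 members higher when adjusted over the list alone. Goblet genes differed downward, with a median of -1.67 (camera adjusted p 1.91e-20) and 4 of 15 members past the threshold, Atoh1 (-1.67), Spink4 (-1.69), Zg16 (-2.13) and Ccl6, which was dim in BRAF G; all 15 passed when adjusted over the list alone. Enteroendocrine genes differed downward as a list (median -1.36, camera adjusted p 1.17e-11; adjusted p = 0.254 with an estimated correlation), with Pcsk1, a prohormone convertase, past the threshold (adjusted p 0.0356; dim in both G groups, so its size is not measured) and 11 of 19 past the threshold over the list alone. The regeneration and YAP response list differed upward (median 0.70, camera adjusted p 0.0142; adjusted p = 0.396 with an estimated correlation) with 0 of 15 members past the threshold over all genes and 3 over the list alone. As 6 of these members were dim in both luciferase gates, the median measures no size. With mouse as a block, Anxa10 and Anxa1 of this list, dim in both luciferase groups, had adjusted p of 0.0357 and 0.0398, against 0.153 and 0.264 without it.

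A difference between the lines was found for 51 genes, 20 higher and 31 lower, with Tns4 (3.33), Ndc1 (1.97) and H1f1 (1.70) among the largest upward and Ano7 (-2.43), Klf4 (-2.25), Gfi1 (-2.24) and Zg16 among the largest downward. Tpm2, dim in BRAF G and luciferase RG, passed upward (adjusted p 0.037). Polr3b, whose mean in luciferase RG lay under the array median, passed upward too, and Myrip, whose means in BRAF G and RG did, passed downward, so no size is given for them. Gfi1 is a transcription factor of secretory progenitors. The ERK output list did not pass (median 0.31, camera adjusted p 0.18); Etv5 of this list differed by -1.49 ± 0.30 (adjusted p 0.041), and Dusp6 by 0.66 ± 0.49 (adjusted p 0.606). When mouse was a block, Ier3 (2.05) and Plaur, dim in luciferase G, passed upward in this list, with adjusted p of 0.0440 and 0.0427, against 0.147 and 0.298 without it. So did Mcm7 (2.07, measured on 1 of 2 luciferase RG arrays; 0.0367 and 0.0543), Nusap1 (1.46; 0.0357 and 0.0630) and Gtse1 (0.95; 0.0441 and 0.0826), while Mptx1 (-2.14, measured on 2 of 3 arrays in BRAF G and in BRAF RG; 0.0195 and 0.212) passed downward. The other lists had camera adjusted p from 0.117 to 0.993, stem cell (median 0.27) and tuft cell (-0.33) among them. Lgr5 (0.63), Ascl2 (0.27), Olfm4 (-0.0095) and Spry4, dim in luciferase G, did not pass. With mouse as a block, 221 genes passed, 110 higher and 111 lower, and they include all 51. Without BRAF mouse 1, 2 or 3 the count was 38, 1 or 3, without luciferase mouse 1 or 2 it was 3 or 0 (limma; 1308 genes at an unadjusted p under 0.05 for the latter). With the RG array alone of luciferase mouse 1 or 2 left out it was 143 or 216. In total, 0 of the 16 genes picked by the fixed rule that passed did so in each of these fits. The regeneration list lost its call without luciferase mouse 2 (camera adjusted p 0.112), and the ERK list passed without BRAF mouse 1 (0.00665) and the stem cell, tuft, Paneth and enterocyte lists without BRAF mouse 3 (0.0217, 0.0217, 0.0218 and 9.04e-05).

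Within the BRAF line, the change from NEG to R was set against the change from G to RG, to see whether red cells differ from the rest in another way among cells low for Lgr5-EGFP than among those high for it. Of 20 leukocyte genes 16 were lower in the R change (18 when adjusted over the list alone; median -2.84, camera adjusted p 4.95e-60), with Gzma (adjusted p 3.6e-06, limma), above the array median on 1 of 3 arrays in G and in RG, and Ccl5, dim in G, among them (adjusted p 7.16e-05). Most of these genes read high in NEG alone, and 10 were dim in both G and RG, so the median measures no size. The cell cycle list differed by a median of -0.43 (camera adjusted p 1.14e-07) with 0 of 32 members past the threshold over all genes and 1 over the list alone. The enteroendocrine list differed by 0.40 (camera adjusted p 0.00906; adjusted p = 0.823 with an estimated correlation) with 0 of 19 members past the threshold. Dusp6 (0.30 ± 0.44, SE; adjusted p 0.982), Olfm4 (-0.35 ± 0.26, adjusted p 0.944) and Lgr5 (0.18 ± 0.45, adjusted p 0.985) did not pass.

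Of 135 genes past the threshold, 133 were lower in the R change and 2 higher, the kinase gene Sgk2 (adjusted p 0.0386, and 0.0565 with mouse as a block) and Grp (adjusted p 0.022), the gene of gastrin-releasing peptide. Laptm5 (adjusted p 0.00068) was measured on 2 of 3 arrays in G and in RG. Ccl4, Itgae, Tyrobp, Cd3d and Cd3e also passed. Like Sgk2 and Grp, they were dim in at least 1 of the 4 gates, so no size is given for these genes. The other lists had camera adjusted p from 0.134 to 0.964; the Paneth list (median -0.52, 0.148) had 0.0312 with mouse as a fixed block and 0.119 as a random one, and a median of 0.00020 without mouse 3. Without mouse 1, 2 or 3 the count was 84, 77 or 75, and 7 of the 10 genes picked by the fixed rule that passed did so whichever mouse, or the R array of mouse 1, was left out, Ccl5, Gzma and Cd3e among them. Without mouse 1 the enteroendocrine list lost its call (camera adjusted p 0.381), and the stem cell (0.0135) and Paneth (3.98e-11) lists passed; the regeneration list passed without mouse 2 (0.0372), and the immediate-early (0.0476) and enterocyte (0.0199) lists without mouse 3.

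G against NEG in the BRAF line compares cells high and low for Lgr5-EGFP that were both low for the transgene. It checks the green gate for such cells only, not for RG. Leukocyte genes were far lower in G: Ccl5 was at least 41.5-fold lower (adjusted p 3.72e-07, limma), Gzma at least 35.1-fold (adjusted p 1.07e-08; above the array median on 1 of 3 G arrays), and Laptm5 changed by -5.23 ± 0.50 (SE; adjusted p 4.59e-06; above it on 2 of 3). Of 20 leukocyte genes 18 fell (19 adjusted over the list alone; median -2.84, or -2.44 with 12 dim genes at their bound; camera adjusted p 5.8e-76). Of 15 goblet genes 5 fell, Tff3 (-0.98), Zg16 (-1.51), Clca1 (-1.44) and Bcas1 (-1.62) among them (10 adjusted over the list alone; median -0.78, camera adjusted p 3.27e-14; adjusted p = 0.0533 with an estimated correlation). The hormone gene Sct fell by 1.35 on the log2 scale (SE 0.25, adjusted p 0.00441). Lgr5 was higher in G in 3 of 3 mice, by 0.70 ± 0.32, and did not pass (adjusted p 0.619). Relative to luciferase G, the mean of the stem cell list was -0.54 ± 0.08 (SD) in BRAF RG and -0.83 ± 0.15 in luciferase RG. Both lay below the -0.38 ± 0.17 of BRAF NEG, although RG was sorted as high for green and NEG as low. These list levels were not compared by a test.

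Of the 234 genes that differed, 232 were lower in G and 2 higher, Kank1 (at least 1.63-fold) and Tmprss4 (0.61). Genes and lists higher in G may depend on the makeup of NEG, with its leukocyte transcripts, which was not tested. The stem cell list was higher in G (median 0.36, camera adjusted p 3.85e-06; adjusted p = 0.0533 with an estimated correlation), as were the Wnt list (0.37, camera adjusted p 0.000535; adjusted p = 0.0599 with an estimated correlation) and the cell cycle list (0.27, camera adjusted p 4.22e-06; adjusted p = 0.0533 with an estimated correlation), each with 0 members past the threshold over all genes or over the list alone. The Paneth list (median -1.46, camera adjusted p 1.07e-08; adjusted p = 0.123 with an estimated correlation) and the enterocyte list (-0.54, camera adjusted p 3.85e-06; adjusted p = 0.283 with an estimated correlation) were lower, with 0 members past the threshold over all genes and 3 each over the list alone. Blocking on mouse, Ang4 (-1.57), Mmp7 (-1.41) and Clps (-1.83) of the Paneth list and Rbp2 (-1.15) and Sis (-1.55) of the enterocyte list passed, with adjusted p of 0.0444, 0.0209, 0.0197, 0.0421 and 0.00977, against 0.0715, 0.142, 0.169, 0.0816 and 0.306 without it. The enteroendocrine list was lower on 1 of 19 members, Sct (3 over the list alone; median -0.35, camera adjusted p 1.75e-05; adjusted p = 0.283 with an estimated correlation). Immediate-early genes and EGF-family ligands were lower (median -0.33, or -0.50 with 2 dim genes at their bound and without 3 dim in both gates, camera adjusted p 0.00233; adjusted p = 0.257 with an estimated correlation), with 0 of 16 members past the threshold and 1 over the list alone. Dusp1 (-1.47) had adjusted p of 0.0741, and 0.00830 with mouse as a block. Among p53 targets and CDK inhibitors Cdkn2b (-1.76, measured on 1 of 3 G arrays) and Trp53inp1 (-1.47) fell (median -0.03, camera adjusted p 0.0489; adjusted p = 0.112 with an estimated correlation). The ERK, tuft, regeneration, heat shock and stroma lists had camera adjusted p from 0.19 to 0.986. With array weights 473 genes passed, and without mouse 2 the count was 135. In all, 9 of the 18 genes picked by the fixed rule that passed did so whichever mouse was left out, Ccl5, Gzma and Laptm5 among them. The p53 list lost its call without mouse 1 or 2 (camera adjusted p 0.0804 and 0.196).

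G cells of the BRAF line were set against G cells of the luciferase line, both low for the red transgene, a comparison in which line and transgene cannot be separated. S100a6 was higher in BRAF G by 3.37 ± 0.23 (SE; adjusted p 3.01e-06, limma), and the acyltransferase gene Mboat1 was at least 3.81-fold higher (adjusted p 0.0469). Fgf1, a fibroblast growth factor, was at least 6.30-fold lower (adjusted p 0.0015; above the array median on 1 of 3 BRAF G arrays), and Pdk4, a kinase that restrains glucose oxidation, was at least 6.03-fold lower (adjusted p 0.0015). Car4, a carbonic anhydrase (-2.97, measured on 1 of 3 BRAF G arrays), Gdpd3 (adjusted p 0.0439) and the carboxylesterase Ces2a (-1.83) were lower as well, and Ddah1 (1.62), Psat1 (1.26) and S100a11 (adjusted p 0.0362) were higher. All 3 BRAF arrays lay on the same side of both luciferase arrays for these genes.

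Only 23 genes passed, 9 higher and 14 lower. The ERK output list was higher in BRAF G (median 0.39, camera adjusted p 2.01e-06; adjusted p = 0.15 with an estimated correlation), with 0 of 19 members past the threshold and 5 over the list alone. The regeneration and YAP response list was higher (median 0.53, or 0.34 with 4 dim genes at their bound and without 3 dim in both groups, camera adjusted p 1.33e-05; adjusted p = 0.15 with an estimated correlation) with S100a6 past the threshold and 2 members over the list alone. The enterocyte list (median -0.59, camera adjusted p 2.01e-06), the Paneth list (-1.01, 0.00243) and the goblet list (0.20, 0.0396) were called with 0 members past the threshold over all genes or over the list alone, and each had adjusted p = 0.772 with an estimated correlation. The other 10 lists had camera adjusted p from 0.239 to 0.564. With other fits the count was far higher: 1054 genes passed with array weights and 383 when these 5 arrays were fitted alone. Without luciferase mouse 1 or 2 it was 1 or 7 and without BRAF mouse 1 or 2 it was 12 or 4. Of the 10 named genes S100a6 alone passed whichever mouse was left out. The goblet list lost its call without BRAF mouse 2 or 3 or luciferase mouse 1 (camera adjusted p 0.0852, 0.356 and 0.170), and the enteroendocrine and heat shock lists passed without BRAF mouse 1 (0.00148 and 0.0284).

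RG cells of the BRAF line differed from RG cells of the luciferase line in many genes, and here too line and transgene cannot be separated. The ERK and regeneration lists were called higher in BRAF RG, though not with an estimated correlation (adjusted p = 0.203 and adjusted p = 0.0886 with an estimated correlation). Higher members were Dusp6 at 1.90 ± 0.35 (SE; adjusted p 0.00276, limma) and Ier3 at 2.47 ± 0.44 (adjusted p 0.00236) of the ERK list, and S100a6 at 3.22 ± 0.23 (adjusted p 5.73e-06) and Anxa10, at least 5.05-fold (adjusted p 0.00214), of the regeneration list. Cell cycle genes were higher, Mcm2 by 1.99 ± 0.20 (adjusted p 9.43e-05) and Plk1, a mitotic kinase, by 1.43 ± 0.19 (adjusted p 0.000483). The goblet and enteroendocrine lists were called lower, though not with an estimated correlation (adjusted p = 0.0886 and adjusted p = 0.284 with an estimated correlation). Atoh1 was at -1.76 ± 0.19 (adjusted p 0.000125) and the hormone gene Gip at -2.80 ± 0.36 (adjusted p 0.000377). Klf4, a transcription factor of differentiated cells, was lower at -1.83 ± 0.28 (adjusted p 0.00114).

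Of 1761 genes past the threshold, 1013 were higher and 748 lower in BRAF RG, and with cyclic loess on top of the deposited normalization 776 of 1695 were higher. The genes picked for the highest log2 differences were S100a6 and Tns4 (3.18), measured in both groups, and Mboat1 (at least 10.6-fold), Ddah1 (at least 8.60-fold) and Atg9b (at least 6.52-fold), dim in luciferase RG. The largest falls were Rnase1 (-3.67), Reg1 (-3.61), H2-Bl (-3.15), Ccl9 (-2.91) and Rep15 (-2.89), with Rnase1 and H2-Bl above the array median on 2 of 3 BRAF RG arrays. Of 32 cell cycle genes 18 rose (21 adjusted over the list alone; median 0.75, camera adjusted p 6.37e-11), the only list whose call held with an estimated correlation. Of 15 goblet genes 13 fell (14 adjusted over the list alone; median -1.42, camera adjusted p 2.43e-12; adjusted p = 0.0886 with an estimated correlation) and of 15 regeneration genes 9 rose (9 adjusted over the list alone; median 1.62, or 1.10 with 6 dim genes at their bound, camera adjusted p 2.38e-06; adjusted p = 0.0886 with an estimated correlation). Of 19 ERK genes 8 rose (11, and 1 fell, adjusted over the list alone; median 0.79, or 0.69 with 3 dim genes at their bound, camera adjusted p 0.00012; adjusted p = 0.203 with an estimated correlation). Of 19 enteroendocrine genes 13 fell (13 adjusted over the list alone; median -1.27, camera adjusted p 2.74e-08; adjusted p = 0.284 with an estimated correlation). Enterocyte (5 of 22 fell, 10 adjusted over the list alone; median -0.91, camera adjusted p 2.59e-05) and Paneth genes (4 of 12 fell, 4 adjusted over the list alone; median -1.48, camera adjusted p 0.000754) had adjusted p = 0.43 with an estimated correlation. The other 8 lists had camera adjusted p from 0.228 to 0.901. Fitted on these 5 arrays alone, 343 genes passed, and 625 with array weights; without luciferase mouse 1 the count was 889 and without BRAF mouse 2 it was 922. Of the 52 genes picked by the fixed rule that passed, 29 passed whichever mouse or luciferase RG array was left out.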

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

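The tests of a difference between the lines and between the gates, and the splits of the samples, were chosen before the data were examined; the tests of explanations below were chosen only after the results were seen.

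The change from G to RG differed between the BRAF and the luciferase line in 51 genes, by a test of the difference itself. The lists that differed were goblet (median log2 -1.67), enteroendocrine (-1.36), cell cycle (0.80) and regeneration and YAP response (0.70), of which the enteroendocrine (adjusted p = 0.254) and regeneration lists (adjusted p = 0.396) lost their calls with an estimated correlation, and the regeneration list without luciferase mouse 2 as well (camera adjusted p 0.112). Of the 15 regeneration genes, 6 lay at or below the array median in both luciferase gates, so that median measures no size. Among named genes, the difference was upward for Tns4 (3.33), Tpm2 (2.11), Ndc1 (1.97), Polr3b (1.79), H1f1 (1.70) and Mcm2 (1.51), and downward for Myrip (-2.49), Ano7 (-2.43), Klf4 (-2.25), Gfi1 (-2.24), Zg16 (-2.13), Ccl6 (-1.81), Spink4 (-1.69), Atoh1 (-1.67), Pcsk1 (-1.55) and Etv5 (-1.49). Tpm2, Ccl6 and Pcsk1 lay at or below the array median in at least 1 of the 4 groups, as did Polr3b and Myrip on average, so their values are differences of log2 intensity and measure no size. Line and transgene are the same factor here, so an effect of the line and an effect of BRAF are both open and untested. Leaving out luciferase mouse 2 left 0 of the 51 (limma; 1308 genes at an unadjusted p under 0.05).

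Within the BRAF line, the change from NEG to R differed from the change from G to RG in 135 genes, again by a test of the difference. The lists that differed were leukocyte (median log2 -2.84, which measures no size, as 10 of the 20 genes lay at or below the array median in both G and RG), cell cycle (-0.43) and enteroendocrine (0.40), the last of which lost its call with an estimated correlation (adjusted p = 0.823) and without BRAF mouse 1 (camera adjusted p 0.381, median 0.12). The named genes were Sgk2 (1.43; adjusted p 0.0386, and 0.0565 with mouse as a block), Grp (1.33), Ccl5 (-5.25), Gzma (-4.98), Laptm5 (-4.94), Ccl4 (-4.26), Itgae (-4.00), Tyrobp (-3.77), Cd3d (-3.36) and Cd3e (-3.08). Each of these lay at or below the array median on some or all arrays of at least 1 of the 4 gates, so the values are differences of log2 intensity and measure no size. Of the 10 splits of the 6 within-mouse differences into 3 and 3, the real one called 114 genes in a fit of these alone. The highest other called 0 (limma, up to 703 genes at an unadjusted p under 0.05). Only 1 of 10 splits gave as many genes, too few splits for a share under 0.05. The other splits mix R and RG changes on each side, which widens the spread, so their low counts were likely in advance.

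The lower leukocyte genes of R against NEG may come from leukocytes in the NEG gate, which was set on green and red fluorescence with no leukocyte marker named. This explanation requires the NEG arrays alone to be high, and the median leukocyte gene differed by 0.11 on the log2 scale between R and G, arrays that do not include NEG. As 11 of the 20 genes were dim in R and 12 in G, a median near 0 decides little. Ccl5, Laptm5 and Gzma had mean log2 intensities of 7.71, 7.93 and 7.72 in R, against 6.75, 7.03 and 6.55 in G. Lyz2, picked here as the member brightest in R, had 10.56 in R, 10.70 in NEG and 9.25 in G. The probes of Ccl5, Laptm5 and Gzma read 5089, 4986 and 4311 intensity units in NEG and 108.2, 132.3 and 96.2 in G. That the transgene also lowers such transcripts within crypt cells cannot be told apart, since 3 of the 20 genes lay above the array median on every G array.

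Luciferase RG differed from luciferase G in cell-type genes with no BRAF transgene present. A lower share of stem cells that raised every other type alike would raise the tuft list too. Its median was -0.50 (-0.37 with 6 dim genes at their bound) while the goblet list's was 2.10. Without luciferase mouse 1 the tuft median was -0.39. The tuft call was lost with the stricter filter and with an estimated correlation (camera adjusted p = 0.275). As the fall was known when this test was chosen, the explanation stays open. As for noise independent between genes, 0 of 10000 random lists matched on intensity had a median as far from 0 as the goblet list. That list was picked after its call in this comparison was seen, so the result restates the call and is no separate support. The test also does not cover noise shared between genes, such as the cell makeup of 2 mice. A red gate that takes in more secretory cells still holding EGFP could be at work in either line, as the goblet list also rose in BRAF RG (median 0.57) and the enteroendocrine list did (0.99), though both lose the call with an estimated correlation. An effect of luciferase or of the red protein stays open and untested.

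The ERK output and regeneration lists were called higher in BRAF G than in luciferase G, gates low for the red transgene, but not with an estimated correlation (adjusted p = 0.15 for each). Whether cells with the BRAF transgene in the G gate raised them is open: members of both lists rose further in BRAF RG (median 0.77), as they would without such cells. For the 23 genes past the threshold it is open as well. Their median change from BRAF G to BRAF RG, in the same direction, was 0.0765 (quartiles -0.225 and 0.231), but noise in the shared BRAF G arrays lowers that median, and genes dim in BRAF G, such as Pdk4, could not be seen to fall further. A difference between the lines stays open and untested.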

How the results depend on the processing

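The alternatives chosen only after the data were seen are normexp with offsets of 16 and 50, the stricter filter, cyclic loess and the single arrays left out; the others were planned. Background correction from detection p-values, a detection filter, and median scaling or cyclic loess in place of the deposited normalization were not run, because the non-normalized table was not used here. A chip as a block was not run, as none is named, and the authors' value table is the table used.

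The count for BRAF RG against G (85) was 168 with mouse as a random block, 201 with mouse as a fixed block (pairing) and 292 with array weights, and ranged from 17 to 59 with a mouse left out. For R against NEG (1332) it was 601 with only the compared groups, 539 at 2-fold or more, and 612 to 1167 with a mouse or array left out. For luciferase RG against G (1261) it was 455 with only the compared groups, 694 at 2-fold or more, and 341 to 1320 with a mouse or array left out. For the difference between the lines (51) it was 18 with normexp and offset 16, 92 with the stricter filter, 221 and 220 with mouse as a fixed and a random block, 109 with only the compared groups, and 0 to 216 with a mouse or array left out. For the difference between the gates (135) it was 85 with the stricter filter and 75 to 123 with a mouse or array left out. For G against NEG (234) it was 124 with the stricter filter, 473 with array weights and 135 to 198 with a mouse left out. For BRAF G against luciferase G (23) it was 15 with normexp and offset 16, 1054 with array weights, 383 with only the compared groups, and 1 to 17 with a mouse left out. For BRAF RG against luciferase RG (1761) it was 625 with array weights, 343 with only the compared groups, 751 at 2-fold or more, and 889 to 1496 with a mouse or array left out. A fold threshold lowers a count by construction, and leaving out mice or groups leaves fewer arrays; where that raised a count, and for the other alternatives, the cause was not tested. With cyclic loess, 678 of 1196 genes were higher in luciferase RG than in G (542 of 1261 without it), and 776 of 1695 in BRAF RG than in luciferase RG (1013 of 1761).

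Of 60 list results past the threshold, 1025 comparisons with an alternative kept direction and call in 954 and lost the call in 71; 40 of these are the correlation estimated from the data, which kept 20 list calls. The other 31, with mice or arrays left out among them, fell on 8 list results, a list counted once per comparison. Goblet in BRAF G against luciferase G ended with cyclic loess, no filter, the stricter filter, the mean of probes, array weights and only the compared groups, and p53 targets in G against NEG with cyclic loess, the mean of probes, array weights, the trended prior and only the compared groups. The mean of probes ended p53 targets and the stricter filter tuft in luciferase RG against G, the stricter filter regeneration in the difference between the lines, and array weights enteroendocrine in the difference between the gates. The immediate-early and Wnt lists in luciferase RG against G ended only without mouse 1 or its RG array. Of 60 list results not past it, 1022 of 1060 comparisons stayed so, 34 passed and 4 reversed. Mouse as a fixed block, in 6 of the 8 comparisons, moved 3 list calls, the Wnt list in R against NEG, the regeneration list in luciferase RG against G and the Paneth list in the difference between the gates; as a random block it moved 0 of 120. Named genes, each counted anew in every comparison that named it, gave 251 results past the threshold. For these, 3526 of 4098 comparisons with an alternative kept the call, 569 lost it and 3 reversed. For the 325 named gene results not past it, 4945 of 5214 stayed so, 256 passed and 13 reversed. Signal over background limits dim genes: fold changes appear to hold background and are bounds where a group lies at the array median.

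The reversed lists were Paneth in R against NEG without BRAF mouse 1 (median -0.327, with 0.460 the highest value, without mouse 2), Paneth in the difference between the gates without BRAF mouse 3 (0.00020, with -1.08 the lowest, without mouse 1), and stroma under the stricter filter in the difference between the lines (0.125) and in BRAF G against luciferase G (-0.0697). With the mean of a gene's probes, Hsp90aa1 reversed in BRAF RG against G (0.0337), R against NEG (0.0800) and BRAF RG against luciferase RG (-0.0615), and Tnfrsf10b in luciferase RG against G (-0.0365), the difference between the lines (0.228) and BRAF RG against luciferase RG (0.352), by construction, as their probes differ in sign. In R against NEG, with a mouse or array left out, Ang4 ranged from -0.0221 to 1.16, Mmp7 from -0.114 to 0.785 and Clps from -0.294 to 0.830, each lowest without BRAF mouse 1, and Tagln from -0.0422 (without BRAF mouse 2) to 0.525. In the difference between the gates, Lgr5 reversed with array weights (-0.316) and Atf3 ranged from -0.346 (without BRAF mouse 1) to 1.60. Without luciferase mouse 2 or its RG array, Vim reversed in the difference between the lines (0.0334 and 0.0711, with -1.01 the lowest value) and in BRAF RG against luciferase RG (0.343 in both, with -0.734 the lowest). For these the cause was not tested beyond the fewer arrays.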

Other observations

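The splits of the samples were planned; the test of gene families was chosen only after the results were seen.

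Splits of the 6 arrays of a comparison into 3 and 3 number 10, too few for a share under 0.05. In each comparison 1 of the 10, the real one, gave as many genes: 85 for BRAF RG against G, with 1 in the highest other; 1332 for R against NEG, with 0 in the highest other (limma; up to 1438 genes at an unadjusted p under 0.05); and 234 for G against NEG, with 0 (up to 585). The real split puts the arrays of each of 3 mice on different sides, as 3 of the other splits do, and those called 0 genes in each comparison (74 to 491 at an unadjusted p under 0.05). Every other split mixes both gates on each side, so a difference between the gates widens the spread there. Few calls were therefore likely in advance, and the low counts do not measure what chance would give.

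Families of genes that share a symbol stem were tested as further lists. Of 265 families of 6 or more tested genes, 11 were called in BRAF RG against G with the preset correlation, and 0 with an estimated correlation. The S100a family had a median of 0.80 (4 of 10 rose; camera adjusted p 1.68e-13, and adjusted p = 0.288 with an estimated correlation) and the annexins, Anxa, one of 0.63 (4 of 12 rose; camera adjusted p 2.02e-12, and adjusted p = 0.261 with an estimated correlation). Some of their members, such as S100a6 and Anxa2, are also in the regeneration list. With the members of the fixed lists left out, 9 of 254 families were called with the preset correlation, S100a (median 0.67, camera adjusted p 2.73e-10) and Anxa (0.46, 3.93e-05) among them, and 0 with an estimated correlation (adjusted p = 0.379 and adjusted p = 0.0940 for these families), so whether families shift together beyond the fixed lists is open. In luciferase RG against G, 25 of 265 families were called with the preset correlation and 0 with an estimated one. Among them, the mitochondrial ribosome families Mrpl (median -0.45, 11 of 46 fell; camera adjusted p 0.000289, and adjusted p = 0.470 with an estimated correlation) and Mrps (-0.53, 7 of 28 fell; camera adjusted p 0.000428, and adjusted p = 0.470 with an estimated correlation) were lower. Mrps was also called lower in BRAF RG against G (median -0.12, camera adjusted p 0.0396, and 0.759 with an estimated correlation).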
